A study of Homo sapiens with 12 samples.

How the data were processed

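RNA sequencing was used to measure transcript levels in 12 libraries from a pair of human metastatic melanoma cell lines, WM9 and Hs294T, which the labels describe as BRAF-mutant. Per the labels, resistant cells of each line were grown in rising concentrations of vemurafenib, an inhibitor of BRAF, and cobimetinib, an inhibitor of MEK, up to 0.4 µM of each, and control cells received the solvent DMSO alone. Each of the 4 groups held 3 replicates that the labels state to be biological. Libraries were made with a stranded mRNA kit, per the labels' protocols. The submitters' processing notes name FastQC 0.12.1, fastp 0.24.0, STAR 2.7.11b, featureCounts and Subread 2.0.8 with the human build GRCh38, without saying what each was used for. The annotation, its release and the strand setting are not given in the sources used here.

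The values deposited by the authors are raw read counts, with 1 column per library and no normalization. The table holds 78932 rows and 12 count columns, and it pairs no row with a gene name or identifier. A feature is therefore named by the number of its row, counted from 1 below the header line, and no gene name was inferred from the order of rows. For this reason gene list tests with camera and fry, a fixed panel of genes and most of the rule for named genes, all set before the data were examined, were not run. Features that overlap or share reads with near-identical copies were not told apart. Of the rule for named genes, the part on both lines was applied without its condition on gene symbols. It ranks features by the smaller of their absolute log2 fold changes in the lines. It requires an adjusted p below 0.05 in both lines, no overlap between the 3 libraries of each group and a mean of at least 10 CPM, which is the count scaled to the effective size of the library, in the higher group. The top 2 of the 8 features planned in each direction are named, since none has a gene name.

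Of the rows, 52409 held at least 1 count and 18615 passed the low-count filter of edgeR (filterByExpr by group, minimum count 10). Rows that did not pass held between 0.107% and 0.381% of the counts of a library. Library totals lay between 16817256 and 22561406 counts, and 3 counts corresponded to between 0.126 and 0.230 CPM after scaling. Counting intervals have a level of 95%, a count of 0 was set against a floor of 3 counts, and both cover counting error only, since reads without molecular identifiers are not independent molecules. With trimmed mean of M-values (TMM) scaling, library factors ranged from 0.746 to 1.37.

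Differences were tested with the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3, limma 3.58.1, robust fit, two-sided, Benjamini-Hochberg adjustment). All 12 libraries entered 1 fit with 4 groups and 8 residual degrees of freedom. A feature is said to be called, higher or lower when its adjusted p was below 0.05. The contrasts were resistant against control in each line, the difference of these effects between lines, and Hs294T control against WM9 control. The contrast between the resistant groups was added after the data were examined, as were counts of on-off features, with at least 10 CPM in all libraries of one group and at most 1 CPM in all libraries of the other. Log2 CPM values for correlations and principal components used a prior count of 2. Shares of counts were compared with a two-sided exact permutation test.

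Replicates were compared before use with a chi-square test of their counts over 14768 features, in which sampling noise alone gives a mean of about 1 per feature. The mean was 3.04 for WM9 control 2 with 3 and 3.23 for Hs294T resistant 2 with 3, and between 36.0 and 145 for all other pairs within a group. All pairs exceeded sampling noise, which does not show that the near-identical pairs are independent samples. All libraries were kept as separate samples, as labelled, and the near-identical pairs were summed in an added alternative.

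The test was checked on simulated counts for 18615 features drawn from the control group means, library sizes and dispersions. Resistant means were set equal to control means except in the changed features. Far fewer features were called than in the data (112 in the simulated WM9 contrast against 11475), which makes the adjustment stricter. The recovered shares therefore hold for a setting with few changes and not for the real contrasts. Simulated counts were also drawn independently, without the spread that features share between replicates in the data and without near-identical pairs. The numbers of false calls are thus no error rate for the real contrasts. For the WM9 contrast, 20% of 100 features changed 2-fold and 86.0% of 100 changed 4-fold were recovered, with 6 false calls. For the Hs294T contrast these shares were 20% and 88.0%, with 5 false calls. For the difference between lines, 8.5% of 200 features changed 2-fold and 67.5% of 200 changed 4-fold were recovered, with 10 false calls.

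Alternatives set before the data were examined were DESeq2 size factors, upper-quartile factors, no low-count filter, a stricter filter of at least 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a separate fit per line, the replicate number as a block, each library left out in turn, an adjusted p below 0.01 and a test against a 2-fold change (glmTreat). Added afterwards were 1 surrogate variable (sva 3.50.0), a fit without both control libraries numbered 1, the sum of near-identical replicate pairs, the replicate number as a block within states, and other cutoffs for on-off features.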

Results

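Transcript levels were measured in 12 libraries, 3 from each of 4 groups: cells labelled WM9 control, WM9 resistant, Hs294T control and Hs294T resistant. WM9 and Hs294T are lines derived from metastatic melanoma. The resistant cells had been adapted to vemurafenib and cobimetinib, which inhibit BRAF and MEK, while control cells received DMSO alone. The series asked how the transcriptomes of resistant cells differ from those of their sensitive controls. Acquired resistance cannot be told apart here from exposure to the drugs or from separate culture. An effect of resistance therefore means the difference between resistant and control libraries. Library totals ranged from 16817256 counts in WM9 control 3 to 22561406 counts in WM9 resistant 2. Between 27338 rows (Hs294T control 3) and 36106 rows (WM9 control 1) had at least 1 count. Features are named by their row number because the table pairs no row with a gene.

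The libraries grouped by their labelled state, and control libraries of the different lines correlated nearly as closely as libraries within a group. The median Pearson correlation of log2 CPM across features was 0.970 between libraries of the WM9 control and Hs294T control groups, within a range from 0.944 to 0.974. It was 0.790 between WM9 control and WM9 resistant, 0.811 between Hs294T control and Hs294T resistant, and 0.856 between the resistant groups. Within groups the medians lay between 0.972 and 0.985. Hs294T control 1 correlated at 0.974 with WM9 control 1 and at 0.968 with Hs294T control 2. Features are not independent replicates, so these correlations describe the libraries only. The labels of line were not checked by any named gene, and every direction given here holds for libraries as labelled.

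**Figure D1:**
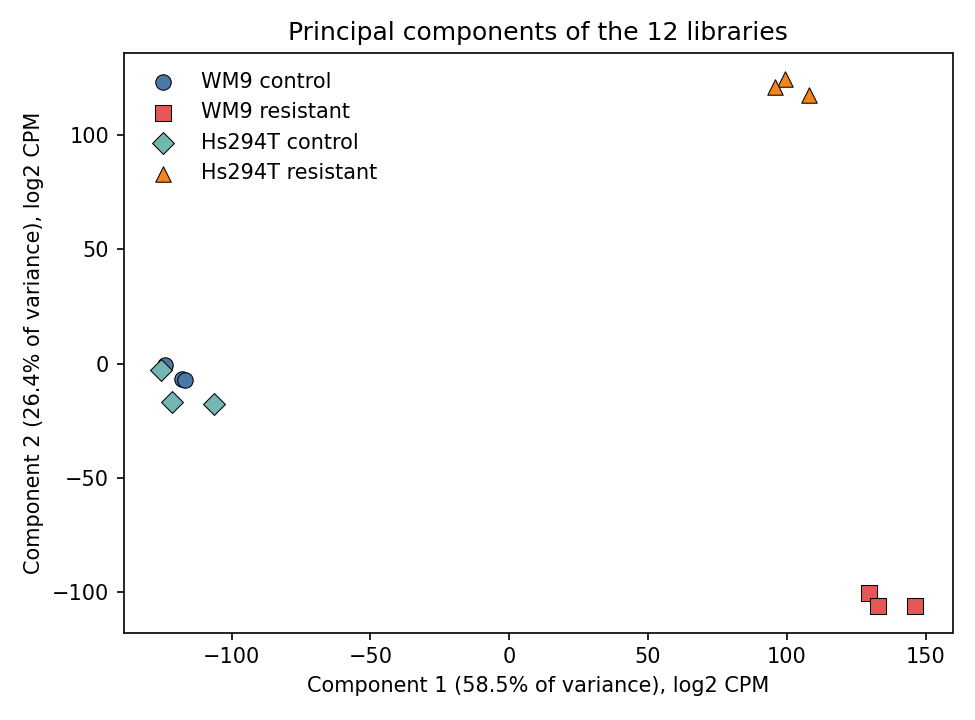
Principal components of the 12 libraries on log2 CPM of the 18615 tested features, with component 1 (58.5% of the variance) on the horizontal and component 2 (26.4%) on the vertical axis, 1 point per library and 1 color and marker per group. The 6 control libraries of both lines lie together, and the resistant groups lie apart from them and from each other.

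In the libraries labelled WM9, 5637 features were higher and 5838 lower in resistant than in control cells, together 11475 or 61.6% of the 18615 tested (edgeR quasi-likelihood test, adjusted p below 0.05, n = 3 per group). At least 2-fold differences were seen in 4620 higher and 4789 lower features, and an absolute log2 fold change of 3 or more in 1468 and 1375. The median absolute log2 fold change of the called features was 1.80. In 66.8% of tested features the 3 resistant libraries did not overlap the 3 control libraries, against 10.0% by chance. On-off features, with at least 10 CPM in all 3 libraries of one group and at most 1 CPM in all 3 of the other, numbered 162 on in resistant and 136 on in control libraries. With a filter of at least 5 CPM in 3 libraries the numbers at least 2-fold higher and lower were 2961 and 2982, and a test against a 2-fold change called 3299 higher and 3064 lower. The balance depended on the scaling, with 5166 higher and 6478 lower under upper-quartile factors (4188 and 5368 at least 2-fold) and 5730 and 5717 under DESeq2 size factors.

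In the libraries labelled Hs294T, 4635 features were higher and 4635 lower in resistant than in control cells, together 9270 or 49.8% of those tested (edgeR quasi-likelihood test, adjusted p below 0.05, n = 3 per group). At least 2-fold differences were seen in 3753 higher and 3484 lower features, and an absolute log2 fold change of 3 or more in 1402 and 1108. The median absolute log2 fold change of the called features was 1.69. Libraries of the groups did not overlap in 58.2% of tested features, against 10.0% by chance. On-off features numbered 159 that were on only in resistant and 124 that were on only in control libraries. The stricter filter gave 2286 higher and 2006 lower features at least 2-fold changed, and a test against a 2-fold change called 2586 higher and 2000 lower. The numbers higher and lower were 5141 and 4579 without a low-count filter and 4010 and 3389 with near-identical pairs summed.

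The share of counts in the most abundant features was compared between states. The 10 most abundant features held 5.08% ± 0.21 of the counts in WM9 control and 8.86% ± 1.21 in WM9 resistant libraries (SD, n = 3 each; two-sided exact permutation p = 0.1). In Hs294T the shares were 5.46% ± 0.76 and 7.53% ± 0.52 (SD, n = 3 each; two-sided exact permutation p = 0.1). In both lines all 3 resistant libraries lay above all 3 controls, and 0.1 is the smallest p that 3 against 3 libraries can give.

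The features shared by both lines were compared next. The contrasts have no library in common, but the control groups were nearly alike, with a median correlation of 0.970. Different resistant groups were thus set against nearly the same baseline. That alone can raise the calls in the same direction and the correlation, so the counts for independent lists do not measure chance here. Both lines had 2873 features higher and 2819 lower in resistant cells, where independent lists of the same lengths would share 1404 and 1454. Opposite directions were found for 464 features higher in WM9 and lower in Hs294T (1404 for independent lists) and for 408 lower in WM9 and higher in Hs294T (1454). Of 6564 features called in both lines, 5692 or 86.7% went the same way. Across all tested features, which are not independent replicates, the log2 fold changes had a Pearson r of 0.576 and a Spearman rho of 0.547. On-off differences common to both lines numbered 55 features on in both resistant and off in both control groups, and 50 the other way round. At an adjusted p below 0.01 the features lower in both lines numbered 1829 and those with opposite directions 233 and 220, and with near-identical replicate pairs summed 259 were higher in WM9 and lower in Hs294T. Without a low-count filter the Pearson r was 0.412.

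The feature row12560 was almost absent from control libraries and was found in all 6 resistant libraries. It had 149.7 ± 62.1 CPM in WM9 resistant and 217.7 ± 33.2 CPM in Hs294T resistant libraries (SD, n = 3 each). The WM9 controls held 1 count in all and the Hs294T controls 2. The ratio of summed counts was 9555 in WM9 (95% counting interval 1714 to 377463) and 6731 in Hs294T (1863 to 55586), with edgeR adjusted p of 1.1e-09 and 1.11e-09.

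The feature row31705 rose from 0.877 ± 0.689 to 4589 ± 1285 CPM in WM9 (log2 fold change 12.32, SE 0.58, edgeR adjusted p = 9.86e-10). In Hs294T it rose from 0.163 ± 0.061 to 3447 ± 348 CPM (log2 fold change 14.33, SE 0.65, edgeR adjusted p = 8.57e-10; SD, n = 3 per group). The log2 fold change in Hs294T exceeded that in WM9 by 2.00 (SE 0.73, edgeR adjusted p = 0.047). The control libraries held 58 counts in all in WM9 and 10 in Hs294T, so this difference rests on low control counts. The mean in resistant libraries was not higher in Hs294T than in WM9. That difference had an adjusted p below 0.05 in 8 of 22 other fits, with adjusted p between 0.0149 and 0.203, and it was 1.16 without WM9 control 2.

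The feature row46532 fell from 33.6 ± 2.19 CPM in WM9 control and 62.9 ± 17 CPM in Hs294T control libraries (SD, n = 3 each) to 0 counts in all 6 resistant libraries. Against a floor of 3 counts over the resistant group, it was at least 592-fold lower in WM9 and at least 1206-fold lower in Hs294T, with edgeR adjusted p of 2.88e-08 and 1.54e-08.

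The feature row74508 fell from 712.6 ± 202.9 to 0.219 ± 0.076 CPM in WM9 (log2 fold change -11.69, SE 0.60, edgeR adjusted p = 1.8e-09). In Hs294T it fell from 1605 ± 787 to 0.222 ± 0.055 CPM (log2 fold change -12.78, SE 0.61, edgeR adjusted p = 1.21e-09; SD, n = 3 per group). Its effects in the lines were not shown to differ (difference -1.09 on the log2 scale, SE 0.88, edgeR adjusted p = 0.362).

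**Figure D2:**
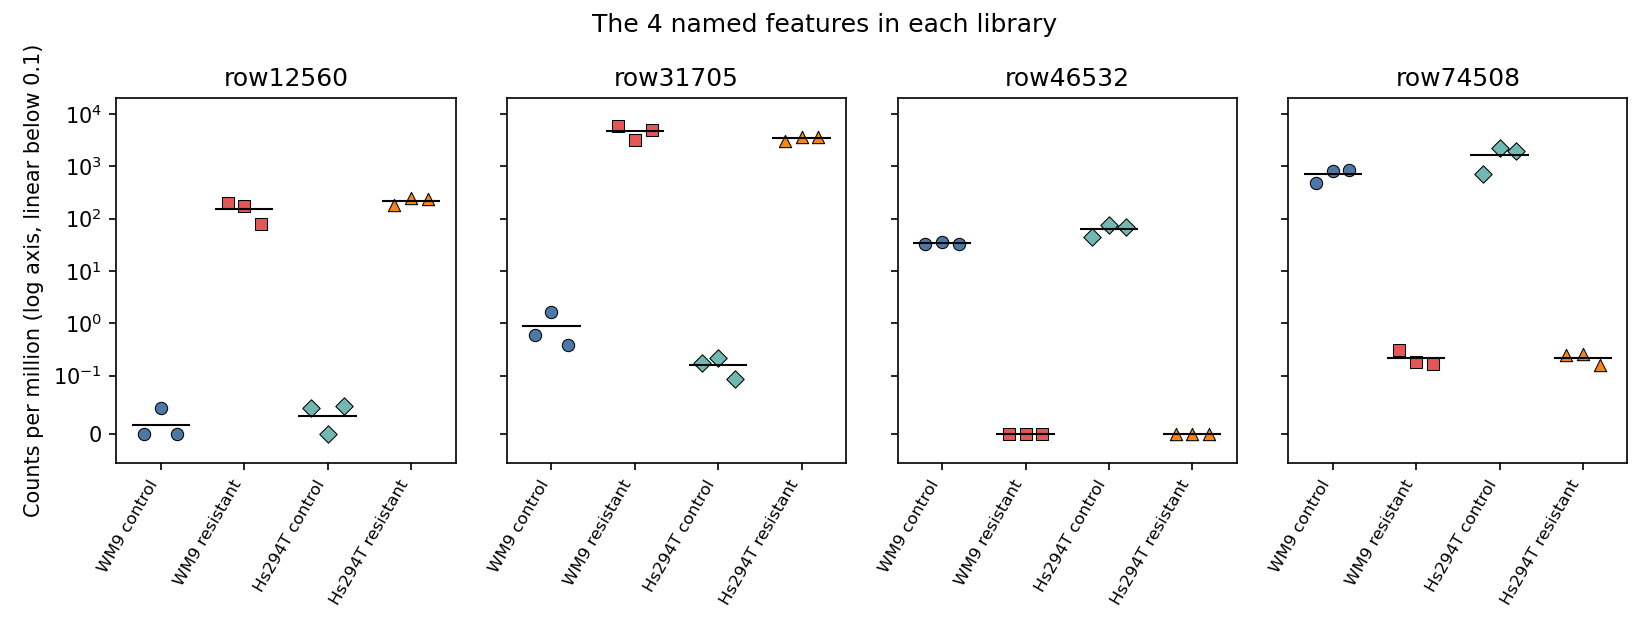
CPM of row12560, row31705, row46532 and row74508 in each library, on a log axis that is linear below 0.1 CPM, with 1 point per library, a line at the mean of each group and the 4 groups along the horizontal axis. The first pair was high in all 6 resistant libraries and the other pair in all 6 control libraries, with 0 counts of row46532 in resistant cells.

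The effect of resistance differed between the lines for 6194 features, 2918 with a higher and 3276 with a lower log2 fold change in Hs294T than in WM9 (edgeR quasi-likelihood test of the interaction, adjusted p below 0.05). All 872 features called in opposite directions were among them. Since the control groups were nearly alike, the difference can largely reflect that between the resistant groups. Of the 5692 features called in the same direction, 1385 had effects of different size and 4307 were not shown to differ. Of 4911 features called in WM9 alone, 2396 passed the test of the difference, as did 1428 of the 2706 called in Hs294T alone. At an adjusted p below 0.01 the numbers were 1623 and 1962, and with the near-identical replicate pairs summed they were 1931 and 1991. Upper-quartile factors turned the balance, with 3348 higher and 2777 lower.

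The control groups of the lines differed in fewer features than the resistant groups or than the states within either line. In Hs294T control against WM9 control libraries, 390 features were higher and 329 lower, together 719 or 3.86% of those tested (edgeR quasi-likelihood test, adjusted p below 0.05, n = 3 per group). The groups did not overlap in 22.8% of features, against 10.0% by chance, and 4 features were on in one control group and off in the other, 2 each way (12 in all at cutoffs of 5 and 0.5 CPM and 2 at 20 and 2 CPM). The numbers higher and lower lay between 139 and 228 and between 159 and 210 when any of WM9 control 1, 2 or 3 or Hs294T control 2 or 3 was left out, and were 928 and 467 without Hs294T control 1. DESeq2 called 739 higher and 546 lower, and 107 and 119 were called by edgeR with near-identical pairs summed.

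The resistant groups differed more widely, in a contrast added after the data were examined. In Hs294T resistant against WM9 resistant libraries, 3859 features were higher and 4044 lower, together 7903 (edgeR quasi-likelihood test, adjusted p below 0.05, n = 3 per group). Upper-quartile factors turned that balance to 4331 higher and 3610 lower, and without a low-count filter it was 4107 and 3951, and with near-identical pairs summed 2947 and 2907. The libraries did not overlap in 53.8% of features, against 10.0% by chance. On-off features numbered 140 that were on only in Hs294T resistant and 85 that were on only in WM9 resistant libraries. No feature was on in both groups of one line and off in both groups of the other, whereas 105 were split in this way by state. A feature split by line must also be on-off between the control groups, where only 4 were found. The absence of such features thus largely restates the likeness of the controls.

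**Figure D3:**
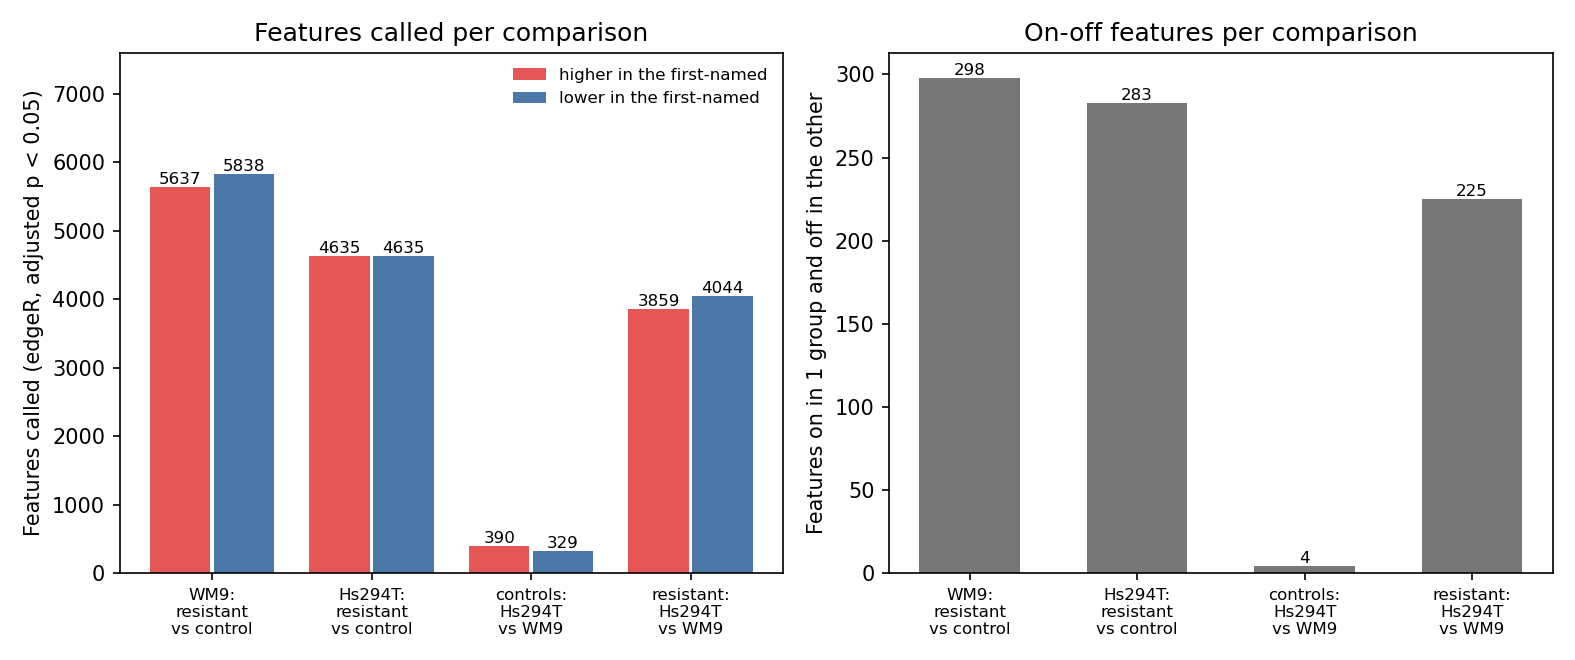
Features called by edgeR in each comparison (left, numbers higher and lower in the group named before the other) and features with at least 10 CPM in all 3 libraries of one group and at most 1 CPM in all 3 of the other (right), with bars that start at 0. The controls differed in 390 and 329 features and 4 on-off features, against 5637 and 5838 and 298 in WM9.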

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

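The tests of an exchange of labels, of a single line behind both control groups, and of the replicate axis, with the library measures beside it, and the contrast between the resistant groups were chosen only after the results were seen. In a test of the difference itself, the effect of resistance was higher in Hs294T for 2918 features and lower for 3276. Of the features called in both lines, 872 went in opposite directions. With control groups nearly alike, this difference can largely reflect that between the resistant groups. It does not settle whether the labels of line are right. The same test gave row31705 a difference of 2.00 on the log2 scale, which rests on low counts in the controls. It fell to 1.16 (edgeR adjusted p = 0.203) without WM9 control 2. The adjusted p also rose above 0.05 when any other library was left out except WM9 control 1, WM9 control 3 and WM9 resistant 1.

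The control libraries of the lines were nearly alike and stood apart from the resistant libraries of their own lines. Features on in both groups of one line and off in both of the other numbered 0, against 105 split by state. That met the bound set against correct labels before these features were counted. Such a feature must also be on-off between the control groups, where only 4 were found. With controls this alike the bound would have been met whatever the resistant groups held, so it restates that likeness and decides nothing further. In the test of an exchange of the WM9 resistant and Hs294T control labels or columns, 6 of the 6 libraries lay closer to the other line's group in the same state, which correct labels with a large effect of state would also give. On-off features between the control groups were 0.0178 of those between the resistant groups, which restates the likeness that raised a single line behind both control groups as an explanation. The profile along the row order, with a control-to-resistant ratio of 0.619, lay between its bounds. That profile is the SD of medians over blocks of 200 features, beyond that of shuffled row orders. It was 0.192 between the controls and 0.310 between the resistant groups. Between the states it was 0.385 in WM9 and 0.303 in Hs294T, where an effect of state would also enter. Correct labels, an exchange and a single line therefore cannot be told apart, since no test here separates them.

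A single axis held 58.4% of the variance between replicates within the 4 groups, and across 10701 features its loading correlated at 0.526 with the log2 difference between the control groups, 0.329 with the WM9 effect and 0.068 with the Hs294T effect. After every library was thinned to the smallest total, the first axis held 58.2%. Among 2258 features with a mean of at least 100 CPM, the first axis held 69.4%. A dominant axis thus remained with equal totals and among abundant features. Each was computed anew and not matched to the axis of 58.4%, and the values were already scaled for library size. Library size and reads in low-abundance rows are therefore not excluded as sources of the axis of 58.4%. Among 4 library measures, taken as deviations from group means over 12 libraries, the log TMM factor followed the axis most closely (Pearson r -0.942, Spearman rho -0.937, exact permutation p = 0.000772 for each, the smallest possible, adjusted p = 0.00309; r -0.912 without the 2 farthest libraries). The share of counts in rows not tested gave r -0.667 and rho -0.594 (exact permutation p = 0.0301 and 0.0725, adjusted p = 0.0602 and 0.139; r -0.558 without the 2 farthest), rows with a count r -0.672 and rho -0.580 (0.0648 and 0.104, adjusted 0.0864 and 0.139; r -0.528), and total counts r 0.064 and rho 0.007 (0.885 and 0.996, adjusted 0.885 and 0.996; r 0.366). The TMM factor is computed from the same counts and scales the values behind the axis. Its relation to the axis is thus partly built in and is no outside measure of a library. The control libraries numbered 1 held 0.381% and 0.289% of their counts in rows not tested, against 0.107% to 0.162% in the other controls, so a difference in RNA composition or quality stays open beside a batch, and no biological explanation was tested.

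Other splits of the libraries were refitted for each count. Each comparison of 3 against 3 libraries has 10 splits, too few for a share below 0.05, and 1 split, the real one, reached the real value in each. The real and the highest other values were 11475 and 0 for WM9, 9270 and 0 for Hs294T, 719 and 0 between the controls, and 7903 and 0 between the resistant groups. Every other split mixes the compared groups and carries their difference as spread, so the counts of 0 do not tell what chance would give. For the difference between lines, 4 of 100 splits drawn from 200, the real one included, called as many features as the real 6194. The test does not settle whether chance gives that number, because 80 of the splits mix states in both lines, carry the effect of state as spread and called 0. The highest other values, 12169, 6901 and 6821, came from splits that keep WM9 as labelled and exchange all 6 or 4 of the Hs294T libraries between states. The large difference between the states as labelled thus enters these counts.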

How the results depend on the processing

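The fits with summed near-identical pairs, the surrogate variable, the block within states, without both controls numbered 1, and all fits of the resistant groups against each other and on-off counts were chosen after the data were examined. Of 550 counts and correlations recomputed under the alternatives, 513 stayed within 1.5 times of the reported count, or within the jackknife error of the correlation and 37 did not. All 192 log2 fold changes of the 4 named features within the lines kept their direction and call. These features were picked for the largest changes called in both lines, so this says nothing about the other features. Gene list tests, with all their alternatives, were not run because no row is paired with a gene.

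Without a low-count filter the Pearson r between lines was 0.412. With the stricter filter, which tests fewer features, at least 2-fold changes numbered 2961 higher and 2982 lower in WM9 and 2286 and 2006 in Hs294T. The test against a 2-fold change called 3064 lower features in WM9 and 2000 in Hs294T. At an adjusted p below 0.01 the difference between lines gave 1623 and 1962 features, the controls 151 and 126, lower in both lines 1829, and opposite directions 233 and 220. DESeq2 called 739 higher and 546 lower between the controls, and the cause was not tested. Leaving out each library in turn gave 139 to 928 higher and 159 to 467 lower between the controls, the highest without Hs294T control 1. Summing near-identical pairs, which leaves fewer samples, gave 1931 and 1991 for the difference between lines, 107 and 119 between the controls, and 259 higher in WM9 and lower in Hs294T. On-off features between the controls numbered 12 at 5 and 0.5 CPM and 2 at 20 and 2 CPM.

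With the replicate number as a block, 309 features were higher in WM9 and lower in Hs294T, and the other counts refitted with it, none of them between control or between resistant groups, stayed within 1.5 times. Deviations of samples with the same number correlated at -0.38, -0.40 and 0.35 in WM9 and -0.52, -0.63 and 0.19 in Hs294T, and across the lines at 0.62, 0.43 and -0.26 in controls and 0.68, 0.62 and -0.01 in resistant cells. Not all numbers correlated above 0.1 in any of these, so the numbers were not taken to pair the samples. A block by number within states gave 1140 higher and 848 lower between the controls, and 4852 and 4742 between the resistant groups. The block within lines ended the call of the difference for row31705 (adjusted p = 0.141). Upper-quartile factors moved the median log2 fold change in WM9 from -0.09 to -0.24 and that of the difference between lines from 0.03 to 0.18. With the surrogate variable the numbers higher and lower were 5860 and 5992 in WM9 and 5430 and 5498 in Hs294T, and without both controls numbered 1 they were 5585 and 5379, and 4727 and 4474. In simulated counts with few changed features, 20 of 100 2-fold changes were recovered in WM9.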

Other observations

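Both tests here were chosen after the pattern was seen. Neighbouring rows of the table moved together between groups, of one state as well as of different states. Among 9190 features with a mean log2 CPM of at least 3, the SD of medians over blocks of 50 consecutive features was 0.576 for the WM9 difference, above 0.265, the highest of 100 shuffled row orders, 0.244 against 0.097 between the controls and 0.395 against 0.158 between the resistant groups. A chance order of rows therefore does not account for it. Among 10701 features with a mean log2 CPM of at least 2, removing the loading of the replicate axis left 0.650 of the excess SD, between the bounds set for and against that axis as the source, so its part cannot be told apart. If the row order follows position in the genome, differences in gene copy number may contribute, which was not tested because rows carry no positions.

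Estimated for each group alone, the biological coefficient of variation was 0.233 in WM9 control, 0.316 in WM9 resistant, 0.348 in Hs294T control and 0.169 in Hs294T resistant libraries. The joint fit of all 12 gave 0.273, by a different estimator. The lowest values, 0.169 and 0.233, belong to the groups that hold a near-identical pair of replicates. They therefore do not show that the cells of these groups vary less.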
